A study of Homo sapiens with 9 samples.

How the data were processed

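Single-cell RNA profiles of human lung were analysed from 9 libraries: 1 of healthy parenchyma, 7 of the upper lobe in idiopathic pulmonary fibrosis (IPF), a progressive scarring disease of the lung, and 1 of the lower lobe in IPF. Per the labels' protocols, tissue was fixed in formalin and embedded in paraffin, cells were released by enzymes, and RNA was read with a 10x Genomics fixed-RNA probe kit for multiplexed samples on the Chromium X instrument. In such a kit probe pairs bind known transcripts, and each bound pair is counted once by its unique molecular identifier (UMI). Per the submitters' processing notes, reads were processed with Cell Ranger 7.1.0 and Seurat on GRCh38 (hg38). The series' design text also names Harmony, PAGA and CellChat for the study's own downstream steps.

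The 18 files hold a raw and a normalized table for each library, and the 9 raw tables were used. Their values are whole-number UMI counts per gene and cell, deposited by the authors without normalization, and the normalized tables were not used here. The tables had been filtered before deposit: no cell had under 202 genes or over 10.0% mitochondrial UMIs. Gene symbols in the tables were matched to GENCODE 44 on GRCh38 for positions, since the tables give no coordinates. Immunoglobulin and HLA genes are not named, because probes for near-identical copies cannot be told apart by symbol.

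The tables differ in which genes they list. Of 17487 genes in any table, 248 were listed in more than 1 library but only within 1 run, and were left out. Runs were inferred from shared droplet barcodes, as given below, and genes listed in a single library were not left out by this rule. Most of these, 221 genes, were listed only in upper-lobe libraries 2 and 7, where they held 2.78% and 1.33% of UMIs. In the fits, a gene that a table does not list was given no value there, instead of 0. Each fit therefore used genes listed in all of its libraries, and clustering used the 11142 genes listed in all 9. In marker scores a marker that a table did not list counted as 0, which lowered that library's score. This affected healthy library 1 and upper-lobe libraries 1 and 2, and KRT18, FCN1, TPSAB1, TPSB2 and SAA1 were not scored in any library. Genes of the Y chromosome and of X inactivation were left out of all tests, as were GSTM1, GSTT1 and UGT2B17, which are often deleted in people.

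The labels name no run or batch. Libraries pooled in 1 run share droplet barcodes, and barcode overlap split the libraries into 4 runs: the healthy library with upper-lobe library 5 and the lower-lobe library; upper-lobe libraries 1, 3 and 4; upper-lobe libraries 2 and 7; and upper-lobe library 6 alone. Overlap within a run was at least 8.58 times the median overlap, and between runs at most 1.60 times. Named gene values of the healthy or the lower-lobe library are therefore also given against upper-lobe library 5, which shares their run, as a difference of 2 libraries with no test (pseudocount 1 CPM, where CPM are counts scaled to a common total for each sum). The titles of upper-lobe library 5 and the lower-lobe library share a code, so both may come from 1 lung, which the labels do not state. The labels also do not state that the libraries come from separate donors, so p-values measure only the spread between these samples.

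Cells were clustered with leidenalg 0.10.2 on a graph of shared neighbours, at resolution 2 (seed 1) and with no batch correction. The graph was built from log-normalized counts, 2000 variable genes, 30 principal components and 15 neighbours. Each of the 49 clusters took the name of the class with the highest mean marker score if that score was at least 0.15, and at least 0.1 above the next class or with more of its markers among the 10 leading genes. These thresholds and the rules for leaving a cluster unnamed were set after the clusters were seen. They left 4 clusters unnamed, which held 0 of 611 healthy cells, a mean of 2.96% of upper-lobe cells and 1.35% of lower-lobe cells. Mesenchymal cells were clustered again at resolution 0.8 into 12 sub-clusters, with genes scaled within each library, and 3 stayed unnamed. Scrublet scores called 12 of 26651 cells (0.0450%) doublets, too few for a usable call, so removal of the top 6% of scores in each library was added.

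Counts were summed per library and cell class, with at least 10 cells per sum, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. DESeq2 1.42.0 was run beside it. Gene lists were tested with camera and fry of limma 3.58.1, camera with its preset and with an estimated correlation. The groups of 1 healthy and 1 lower-lobe library have no replicate: the spread comes from the 7 upper-lobe libraries, and the lone library is assumed to vary like them. A lone library interchangeable with the 7 would have all of them on one side for 25% of genes. The shares of such genes are given beside each comparison as description and are no test. Mesenchymal cells with at least 1 CTHRC1 UMI were compared with those without one inside each upper-lobe library, with library as a block. CTHRC1 is the gate there and no result. Ligand and receptor genes were compared between mesenchymal cells and the mean of 4 other classes, also with library as a block. Shares of cells have exact Clopper-Pearson intervals at 95%, and a count of 0 allows up to 3 counts. Intervals and floors cover counting error only.

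Shares of cells with a CTHRC1 UMI depend on depth, so each cell with at least 500 UMIs was reduced to 500. The expected share over all such reductions leads, from the hypergeometric distribution, beside 1 fixed random draw with its interval and the range over 100 draws. The way draws were seeded was changed after draws had been seen. Lymphoid cells were chosen as the background, and after their value was seen they were split into T and NK, B and plasma cells, since plasma cells held CTHRC1 UMIs.

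On simulated data with the real libraries' means and sizes and 200 changed genes, the healthy comparisons recovered 0% of 2-fold changes and at most 1.61% of 4-fold and 1.56% of 8-fold changes, and made 0 false calls. The lower-lobe comparison of mesenchymal cells, on 11168 genes, recovered 0%, 4.69% and 30.9% at 2, 4 and 8-fold with 5 false calls. That of epithelial cells, on 11385 genes, recovered 0%, 3.03% and 19.4%. The CTHRC1 comparison, on 8647 genes, recovered 82.4%, 90.3% and 87.1% with 8 false calls.

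Groups, tests, gene lists, markers, alternatives and the rule for named genes were chosen before the data were examined, except where stated. The rule named, per comparison, the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 20 CPM and the same direction in every library, up to 4 members of each list with the smallest p, and a few fixed genes. Where no gene passed, it named the 5 highest and the 5 lowest values, of which 1 in myeloid cells is not reported here. CA4, one of the fixed genes, could not be tested in endothelial cells, since not all tables list it. BANK1 in epithelial cells and CD14 in endothelial cells fall outside the rule and were chosen after their values were seen.

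Alternatives were another scaling (RLE size factors), no filter on low counts, the DESeq2 Wald test, cells with at least 500 genes, classes by marker score, Scrublet calls removed, sums of at least 30 cells, leaving out libraries, no library block, at least 2 CTHRC1 UMIs, fibroblasts only, thinned cells, unthinned shares, a sub-clustering resolution of 1.6 and the lower-lobe library counted among the IPF libraries. Chosen after the data were seen were the top doublet scores, leaving out upper-lobe libraries 6 and 7 together, unlisted genes counted as 0, depth-matched cells, a sub-cluster led by genes of other classes left out, lymphoid cells split into their kinds, and run as a block in the healthy and lower-lobe comparisons. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.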

Results

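After filtering by the submitters, the 9 libraries held 26651 cells. The healthy library had 611 cells with a median of 837 UMIs, and the lower-lobe library had 4881 cells with a median of 1078. Upper-lobe libraries 1 to 7 had 333, 1086, 3660, 3274, 4779, 3674 and 4353 cells, with medians of 736, 885, 5446.5, 2233.5, 1268, 1339 and 876 UMIs. Library 3 alone held 44795902 UMIs, against 346716 in library 1. The median share of mitochondrial UMIs was 0.531% and 0.213% in upper-lobe libraries 6 and 7, against 1.35% to 5.19% in the other libraries. In libraries 6 and 7 the leading gene held 0.750% and 0.787% of UMIs, against 1.94% to 8.36% elsewhere, so their profiles were flatter.

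Mesenchymal cells, the fibroblasts and mural cells that build scar tissue in fibrotic lung, made up 26.6 ± 5.15% of cells (mean ± SD, n = 7) in upper-lobe libraries. Their share was 9.98% (7.72 to 12.6%) in the healthy library, below all 7, and 30.3% (29.0 to 31.6%) in the lower-lobe library. Lymphoid cells held 18.4 ± 10.7% of upper-lobe cells, 5.24% of healthy cells and 28.0% of lower-lobe cells. Myeloid cells, which include macrophages, monocytes and dendritic cells, held 14.2 ± 7.51%, 37.8% (33.9 to 41.8%) and 13.2%, and the healthy share lay above all 7 upper-lobe shares. Epithelial cells held 25.5 ± 9.05%, 29.6% and 10.4% (9.58 to 11.3%), and the lower-lobe share lay below the upper-lobe range of 14.8 to 41.6%. Endothelial cells held 10.8 ± 1.75%, 16.7% and 14.8%, and mast cells 1.63 ± 1.32%, 0.655% and 1.88%. In upper-lobe library 5, which shares its run with the healthy and lower-lobe libraries, the shares were 28.8% mesenchymal, 20.03% lymphoid, 12.03% myeloid, 25.0% epithelial, 9.31% endothelial and 4.23% mast cells. By marker scores mast cells held 3.04% in the upper lobe, 1.80% in the healthy and 2.34% in the lower-lobe library. When classes were read from marker scores, the healthy endothelial share of 13.4% lay inside the upper-lobe range of 7.24 to 14.3%. Shares were not tested between groups: an exact permutation test of 1 against 7 cannot reach 0.05, and a test that borrows the spread of the 7 was not run. Release of cells from fixed tissue differs between cell types.

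**Figure D1:**
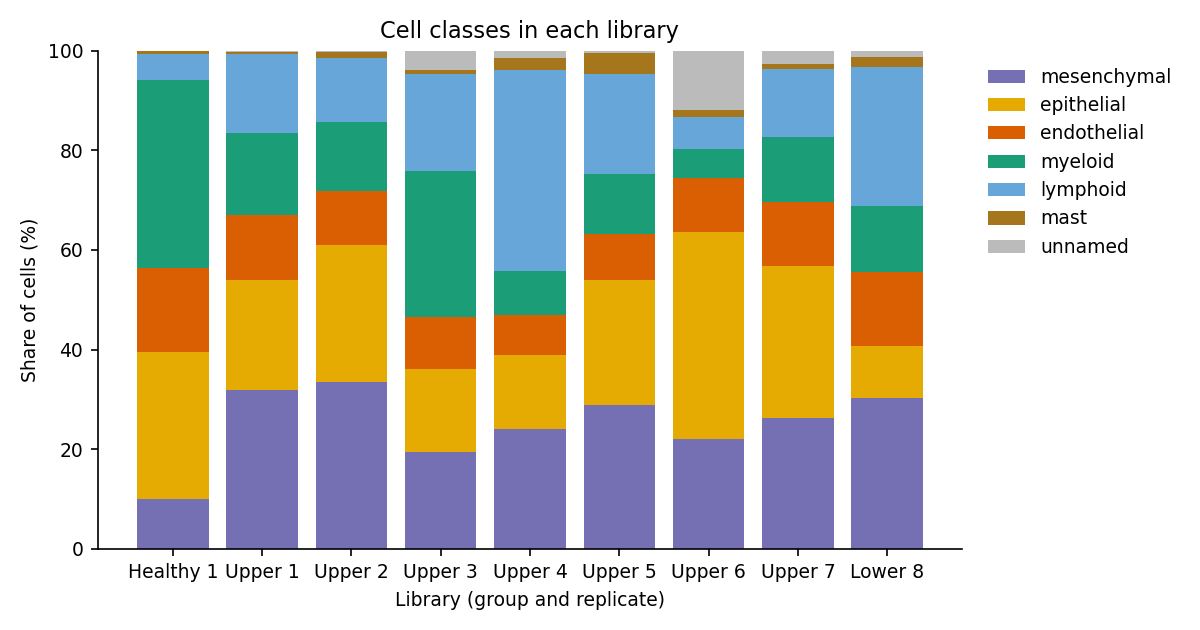
Share of each cell class in the cells of each of the 9 libraries.

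Within mesenchymal cells, sub-clusters were named from markers of known lung subtypes, and they are given as description only. Fibroblasts with markers of fibrosis held 24.3 ± 22.9% of upper-lobe mesenchymal cells, from 3.41% to 69.8% in library 3. They held 6 of 61 healthy cells (9.84%, 3.70 to 20.2%) and 31.6% of lower-lobe cells. Alveolar fibroblasts, which support the air sacs, held 23.6 ± 12.1% in the upper lobe, 34.4% in the healthy and 20.1% in the lower-lobe library. Smooth muscle held 13.7 ± 9.19%, adventitial fibroblasts 6.64 ± 3.91% and pericytes 4.13 ± 1.55% of upper-lobe mesenchymal cells, and 27.6 ± 6.35% stayed unnamed. In library 5, of the same run as the healthy and lower-lobe libraries, fibrosis-type fibroblasts held 22.1% and alveolar fibroblasts 34.4%. The sub-cluster with most of these fibrosis-type cells, 1006 cells led by BMP5, MOXD1 and PIEZO2, scored 0.380 for fibrosis and 0.348 for alveolar fibroblasts, so it was named by the tie rule alone. At a higher resolution the fibrosis-type share was 11.1 ± 5.72% in the upper lobe, with 18.8% in library 3, and 22.6% in the lower lobe, and adventitial fibroblasts held 11.1% in the upper lobe.

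CTHRC1 encodes a secreted collagen-triple-helix protein that marks matrix-producing fibroblasts of scarred lung. At 500 UMIs per cell, the expected share of mesenchymal cells with a CTHRC1 UMI was 17.2%, 9.42%, 17.2%, 9.21%, 3.66%, 5.03% and 1.28% in upper-lobe libraries 1 to 7, a mean of 8.99 ± 6.29%. The healthy library had an expected 7.63%, inside that range, and its draw gave 4 of 58 cells (6.90%, 1.91 to 16.7%, 1.72 to 13.8% over 100 draws). The lower-lobe library had an expected 20.2%, above all 7, with 307 of 1458 cells in its draw (21.1%, 19.0 to 23.2%, 18.5 to 21.9% over 100 draws). Upper-lobe library 5, from the same run, had 3.66%, below both. The intervals of the draws in upper-lobe library 1 (9.75 to 26.3%, 89 cells) and library 3 (14.5 to 20.1%) overlapped that of the lower-lobe library. Counting error alone therefore does not set the lower-lobe share apart from these 2 libraries. Lymphoid cells, meant as a background, had 2.49 ± 2.48% in the upper lobe, 3.94% in the healthy and 2.62% in the lower-lobe library. Plasma cells carried most of it (5.98% in the upper lobe, 6.43% in the healthy and 6.34% in the lower-lobe library), against 1.12% of upper-lobe T and NK cells (5.41% in library 2, from 11 cells, and at most 0.721% in each other library), 1.02% of lower-lobe ones and 0 of 12 such healthy cells, so the lymphoid class as a whole was no clean background. In upper-lobe library 7 plasma cells had 15.1% and endothelial cells 1.92%, both above the mesenchymal share of 1.28%, while T and NK cells had 0.276% and epithelial cells 0.234%. Plasma cells were also above mesenchymal cells in library 5 (7.46% against 3.66%) and in library 6 (11.8%, from 45 cells, against 5.03%). In libraries 5, 6 and 7 a CTHRC1 UMI therefore did not set mesenchymal cells apart from all other classes. Without reduction to 500 UMIs the shares were 18.5 ± 15.8% in the upper lobe, 14.75% in the healthy and 35.3% in the lower-lobe library, and upper-lobe library 3, the deepest, had 48.9%, above the lower lobe. The shares were not tested between groups.

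**Figure D2:**
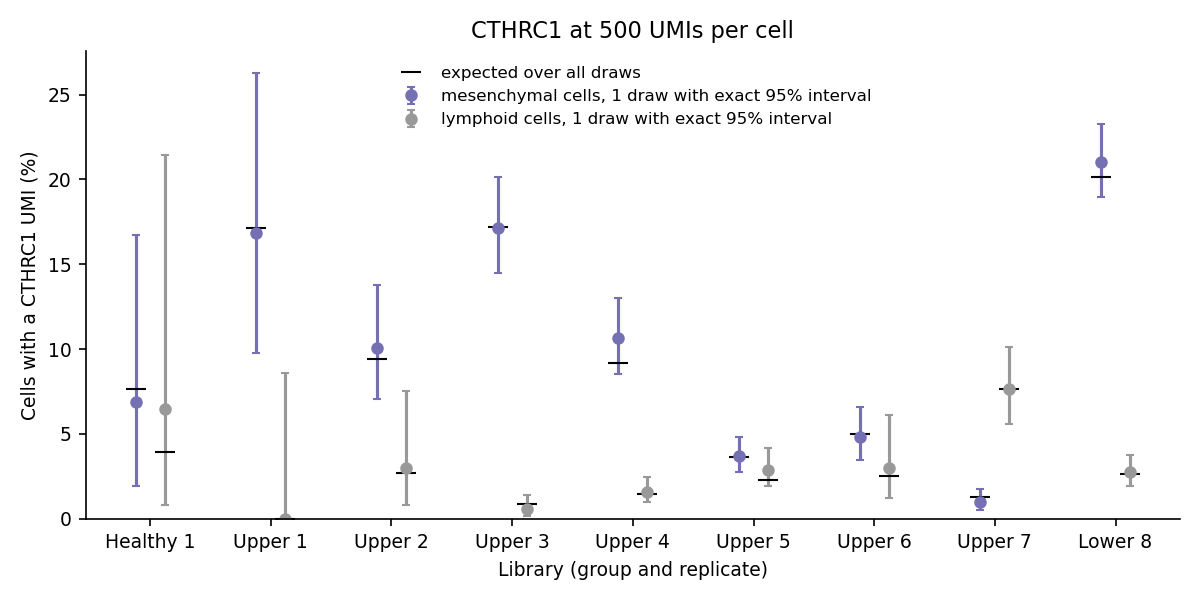
Share of mesenchymal and lymphoid cells with a CTHRC1 UMI at 500 UMIs per cell in each library, from 1 draw with exact 95% intervals; dashes mark the expected share.

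Upper-lobe mesenchymal cells with a CTHRC1 UMI carried higher levels of genes for scar matrix than mesenchymal cells of the same library without one. MMP11, a secreted protease of tissue remodelling, and POSTN, an adhesive matrix protein of scars, rose most, beside COL1A1, the main collagen of scar. LRRC17, ASPN and COL12A1, which encode secreted or fibril-bound matrix proteins, rose as well. MMP11 was at 146 ± 137 CPM with and 8.07 ± 5.95 CPM without a CTHRC1 UMI (log2 3.34 ± 0.33, n = 7, higher in 7 of 7, adjusted p = 1.12e-12, edgeR quasi-likelihood test, Benjamini-Hochberg). POSTN was at 1256 ± 918 and 170.1 ± 188 CPM (log2 3.22 ± 0.24, 7 of 7, adjusted p = 1.81e-17, edgeR), and COL1A1 at 39181 ± 15814 and 6278 ± 3927 CPM (log2 2.72 ± 0.29, 7 of 7, adjusted p = 1.55e-11, edgeR). LRRC17 (log2 2.60), ASPN (2.36) and COL12A1 (2.26) rose in all 7 libraries too. Of 8932 genes tested, 732 passed (288 higher, 444 lower, 1718 at unadjusted p under 0.05), 314 of them in the same direction in all 7 libraries, and DESeq2 passed 397. The count depended on single libraries: it was 308 without library 4, 456 without library 3 and 755 without library 1. It was 7 with no library block, which leaves the large differences between libraries in the error. Cells with a CTHRC1 UMI were deeper, with a median of 8862 against 2288 UMIs in library 3, and the count was 72 with cells thinned to one depth and 195 of 1770 genes tested with cells matched on depth. In the lower-lobe library 708 of 732 genes (96.7%) had the same sign, and in the healthy library, with 9 cells holding a CTHRC1 UMI, 447 of 703 listed genes did.

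Many, but not all, genes for fibril collagens and for folding and linking collagen rose in these cells. Among fibril collagens and their partners 13 of 16 genes rose, including COL3A1 (log2 2.24, 7 of 7) and THBS2 (1.68, 7 of 7), and 15 passed when adjusted over the list alone. In collagen processing 11 of 19 genes rose (13 over the list alone), with P4HA3 (1.96, 6 of 7), LOXL2 (1.45, 7 of 7), which links collagen fibres, and the collagen chaperone SERPINH1 (1.13, 6 of 7). Of the other genes on the fibrosis-fibroblast list 5 of 5 rose, among them COMP (1.63, 7 of 7) and COL8A1 (1.63, 6 of 7). Among matrix proteases 5 of 11 rose and 2 fell (6 and 2 over the list alone), with CTSK (0.90) and MMP14 (0.94) up and ADAMTS4 (−1.57) down in 7 of 7 libraries each. These 4 lists passed camera with its preset, but not with an estimated correlation: adjusted p = 0.0562 with an estimated correlation for fibril collagens, 0.0732 for collagen processing, 0.0518 for the fibrosis-fibroblast list and 0.0732 for proteases. By fry the adjusted p was 0.0115 for fibril collagens, 0.0408 for collagen processing, 0.0115 for fibrosis fibroblasts and 0.0147 for proteases. Unfolded-protein genes had 4 of 14 higher (4 over the list alone, adjusted p = 0.369 with an estimated correlation), with CALR (0.73), PDIA6 (0.67), MANF (0.60) and SDF2L1 (0.83), which serve secretion. Plasma markers, from cells that also secrete heavily and held CTHRC1 UMIs, rose for 2 of 5 genes (3 over the list alone), and plasma RNA was not separated from these values. Basement-membrane genes split, with NID2 (0.89) and COL15A1 (0.62) up and LAMA5 (−0.83) and NID1 (−0.72) down among 14 (3 up and 4 down over the list alone). LAMA5 did not fall with smooth muscle cells and pericytes left out (0.0721, not past the threshold).

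Genes of muscle and mural cells were among those that fell most in these cells. LDB3, which anchors contractile filaments, fell from 206 ± 308 to 42.3 ± 72.3 CPM (log2 −3.33 ± 0.29, n = 7, lower in 7 of 7, adjusted p = 1.54e-14, edgeR quasi-likelihood test, Benjamini-Hochberg). The mural adhesion gene MCAM (−2.45), the potassium channel gene KCNK3 (−2.31), KLHL23 (−2.27), the filament gene SYNM (−2.09) and TMEM74B (−2.09) fell in all 7 libraries. All 8 smooth muscle genes fell (8 over the list alone, fry adjusted p = 0.0139, adjusted p = 0.0732 with an estimated correlation), among them MYH11 (−1.91), DES (−1.43), CNN1 (−1.14) and ACTA2 (−0.96). Of 5 pericyte genes 3 fell (5 over the list alone, adjusted p = 0.239 with an estimated correlation): CSPG4 (−1.60, lower in 5 of 7), RGS5 (−1.37, 6 of 7) and NOTCH3 (−0.58, 6 of 7). The cells without a CTHRC1 UMI were a mixture that held muscle cells and pericytes. A comparison of fibroblasts only left out cells named smooth muscle or pericytes and kept unnamed cells. The cells left out were named from markers that include the muscle and pericyte genes given next, so the values of those genes are no independent test. Among fibroblasts only, ACTA2 rose with log2 1.08 (7 libraries, adjusted p = 6.95e-08, edgeR) and NOTCH3 with 0.79 (adjusted p = 6.19e-04, edgeR), while CNN1 (0.69), DES (0.54), MYH11 (0.37), RGS5 (0.14) and CSPG4 (0.11) did not pass and lay above 0. COL1A1, POSTN and MMP11 stayed past the threshold there. In libraries 1 and 7 only 25 and 22 cells held a CTHRC1 UMI, and their values for MCAM, MYH11, DES and CNN1 (library 1) and P4HA3, SOD2 and PDIA6 (library 7) lay farthest from the other libraries because those cells held no UMI of these genes, so they are bounds set by the pseudocount.

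Some markers of alveolar fibroblasts, the resident cells of the healthy air sac, fell in cells with a CTHRC1 UMI. FGFR4 (log2 −1.19, lower in 7 of 7), INMT (−1.09, 7 of 7), LIMCH1 (−0.69, 6 of 7) and TCF21 (−0.57, 6 of 7) made up 4 of 10 alveolar genes that fell (6 over the list alone, fry adjusted p = 0.00266, adjusted p = 0.0518 with an estimated correlation). Early stress genes NR4A1 (−1.31) and FOS (−0.97) were among 5 of 17 that fell (6 over the list alone, fry adjusted p = 0.0147, adjusted p = 0.152 with an estimated correlation). The inflammatory genes ICAM1 (−0.80), CCL2 (−0.80) and SOD2 (−0.63) fell, 3 of 6 on their list (1 up and 3 down over the list alone), and so did IRF1 (−0.79), 1 of 14 interferon genes. Complement genes C7 (−0.75) and CFD (−0.60) fell, 2 of 11. Adventitial genes split, with DPT at 1.12 and SCARA5 at −0.82 among 7 (2 up and 1 down over the list alone). Of 12 p53 and senescence genes BAX (0.84) and PHLDA3 (0.79) rose (3 over the list alone). Of 11 hypoxia genes PKM (0.64) rose and VEGFA (−0.60) fell.

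Signal genes also differed inside the mesenchymal class. SFRP4 (log2 1.76, higher in 7 of 7), WNT5A (1.39, 7 of 7) and WIF1 (0.96, 6 of 7), secreted modulators or ligands of WNT signalling, rose as 3 of 11 WNT genes (4 up and 1 down over the list alone, adjusted p = 0.0732 with an estimated correlation). INHBA (1.12, 6 of 7), an activin subunit, and LTBP1 (0.66, 7 of 7), which stores latent TGF-beta in matrix, rose, while BMP2 (−1.63, lower in 5 of 7) fell, among 13 genes of that family (3 up and 3 down over the list alone). Among 13 growth factors PDGFD (1.32) and PDGFC (0.85) rose and FGF2 (−0.76) and PDGFA (−0.85) fell, 3 up and 3 down in all (4 and 4 over the list alone). The fall of PDGFA was not seen among fibroblasts only (0.17, not past the threshold). EFNA5 (0.84) was the only gene of 12 in the semaphorin, notch and ephrin list to rise. Of 40 receptor genes 4 rose and 4 fell (5 and 4 over the list alone), with the collagen receptor ITGA11 (1.51) and SDC1 (1.28) up and ITGA1 (−0.77) down. SDC1 is also a gene of plasma and epithelial cells (379.9 CPM in lymphoid, 345 CPM in epithelial and 27.2 CPM in mesenchymal cells), and plasma markers rose in the same cells. Genes that respond to TGF-beta split, with TGFBI (1.40) and PMEPA1 (1.03) up and THBS1 (−0.91) down among 13. In the lower-lobe library VEGFA (0.14), WIF1 (−1.29) and EFNA5 (−0.07) had the opposite sign, which was not tested.

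**Figure D3:**
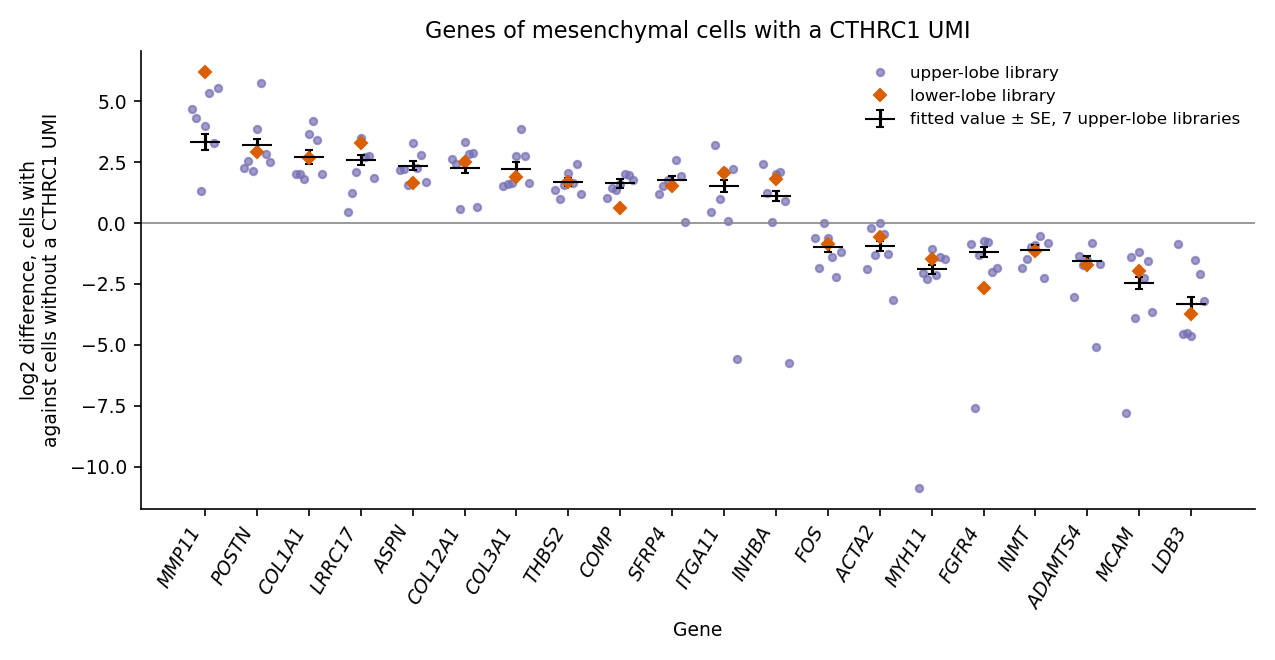
Log2 difference of 20 genes between mesenchymal cells with and without a CTHRC1 UMI: points are upper-lobe libraries, bars the fitted value ± SE, and diamonds the lower-lobe library.

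Mesenchymal cells had the highest mean level, among 5 classes of the upper lobe, of 46 of 123 signalling genes tested. FGF7, a fibroblast growth factor that acts on epithelium, BMP5, and the WNT modulators SFRP2 and SFRP4 were far above the mean of epithelial, endothelial, myeloid and lymphoid cells, as was the ligand gene WNT2. FGF7 stood at 342 ± 114 CPM in mesenchymal cells (log2 5.10 ± 0.20 against the mean of the 4 classes, 7 of 7 libraries, adjusted p = 1.01e-20, edgeR quasi-likelihood test, Benjamini-Hochberg), SFRP2 at 1299 ± 898 CPM (log2 5.08 ± 0.25) and BMP5 at 260.4 ± 56.5 CPM (log2 5.07 ± 0.18, 7 of 7, adjusted p = 5.00e-21). WNT2 (4.89), SFRP4 (4.88), the guidance gene SLIT2 (4.61), LTBP1 (4.58), ANGPT1 (4.53), SLIT3 (4.51), CHRDL1 (4.46), HGF (4.31), SEMA3D (4.17, highest in mesenchymal cells in 6 of 7), DKK3 (3.01), CXCL12 (3.44, highest in 5 of 7) and CCL19 (3.38) were also higher. Among receptors ROR2 (4.82), FGFR4 (4.37), FZD7 (3.72) and the collagen receptor DDR2 (3.08) were higher. Other signals were lower in mesenchymal cells: AREG (−2.51), CXCL3 (−2.21) and EREG (−1.69) were highest in myeloid cells, BMP6 (−2.25) in endothelial cells, CXCL2 (−2.18) in epithelial cells and CCR2 (−2.12) in lymphoid cells. AREG, a growth factor of tissue repair, was at 231 CPM in myeloid and 21.7 CPM in mesenchymal cells. The classes came from clustering these same counts, and BMP5, SFRP2 and SFRP4 were among the leading genes of mesenchymal clusters. The p-values between classes are therefore not independent of how the cells were grouped.

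Against the mean of the 4 classes, 82 of the 123 genes were higher, the 46 among them, and 24 lower in mesenchymal cells (108 in all over the lists alone, 107 by DESeq2, 96 with no library block), against 6400 of 11332 genes over the whole fit, so classes differed in most genes. By list, higher and lower counts were 12 and 3 for TGF-beta and BMP, 12 and 4 for growth factors, 10 and 0 for WNT, 8 and 5 for chemokines (8 and 6 over the list alone), 12 and 4 for semaphorin, notch and ephrin genes (12 and 5 over the list alone) and 28 and 8 for receptors. Ligand and receptor levels were measured, and binding or signalling between cells was not.

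**Figure D4:**
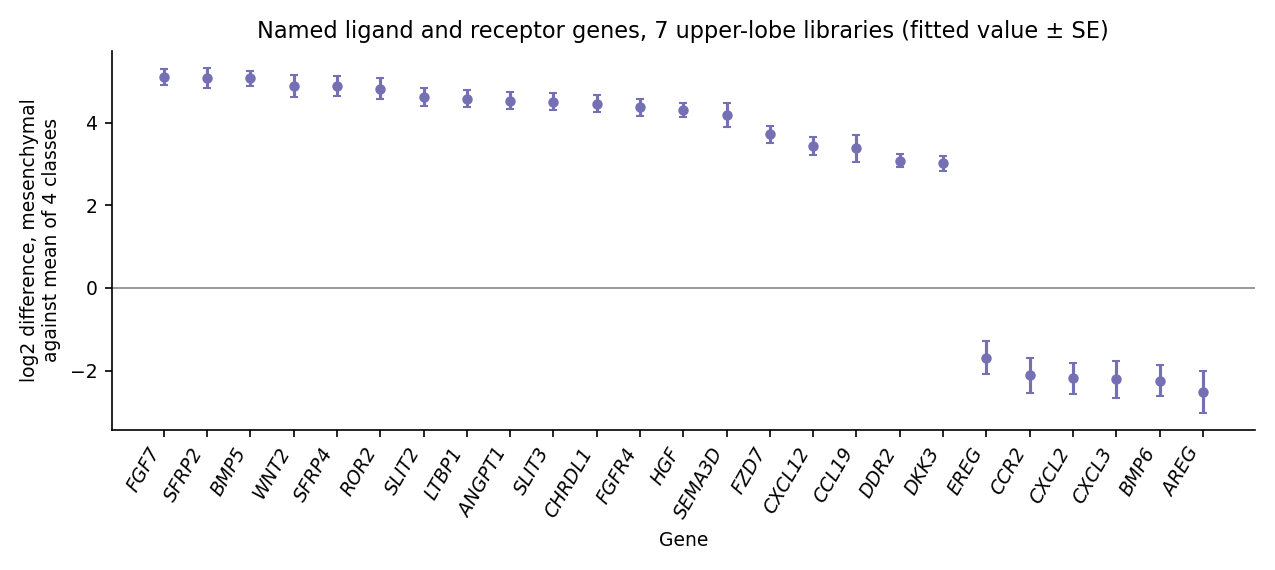
Fitted log2 difference ± SE of 25 ligand and receptor genes between mesenchymal cells and the mean of 4 other classes in the upper lobe.

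Mesenchymal cells of the healthy library had higher values of 3 heat-shock genes and of FCN3 and RAMP3 than the upper lobe, and POSTN was lower there. HSPA1B (log2 −3.81 upper lobe minus healthy, −3.96 against library 5), HSPA1A (−2.74, −2.21) and HSPH1 (−2.07, −2.76), which encode stress chaperones, were higher in the healthy library than in all upper-lobe libraries. FCN3 and RAMP3, genes of lung endothelium, were at −4.00 ± 0.99 (33.8 ± 32.8 v 569 CPM, same run −4.59) and −3.64 (same run −4.43), beside LTF (−3.96, −5.18), PCOLCE2 (−3.60, −2.60) and ACKR3 (−2.46, −1.83). In the healthy library 14.8% of mesenchymal cells lay in a sub-cluster led by genes of other classes, against 6.21% to 19.5% in upper-lobe libraries. Free RNA or doublets were not separated from the FCN3 and RAMP3 values. POSTN was higher in 6 of 7 upper-lobe libraries (2.49 ± 1.82, 463 ± 422 v 81.3 CPM, same run 1.29), while COL1A1 (−0.64 ± 1.42, 14659 v 22772 CPM, same run −1.68) and COL3A1 (−0.91, −2.02) were lower. CTHRC1 (−0.12 ± 1.15, 358 ± 259 v 390 CPM, same run −1.24, 3 libraries above and 4 below) and ACTA2 (0.08, same run 0.36) were close to equal, and leaving out single libraries turned the sign of both. SLC19A2, CORO1C, GADD45G, AKAP8L and CARMIL1 had no UMI in healthy mesenchymal cells, so against a floor of 48.8 CPM they were at least 4.82, 3.68, 3.21, 2.76 and 2.69-fold higher (library 5 at 218, 141, 58.9, 61.0 and 185 CPM). By edgeR's quasi-likelihood test 0 of 10880 genes passed (525 at unadjusted p under 0.05, DESeq2 0, smallest adjusted p 0.851). Stress genes passed camera with its preset (5 of 18 higher, 3 lower over the list alone, adjusted p = 0.617 with an estimated correlation). The healthy sum held 61 cells and 61045 UMIs, and 67.2% of its cells lay in a cluster that also led in upper-lobe libraries 1 and 2, while libraries 3 and 4 were led by another and libraries 5, 6 and 7 by 1 each. The spread came from the 7 upper-lobe libraries, and the lone library was assumed to vary like them. All 7 lay on one side of it for 43.1% of tested genes, against 25% for an interchangeable library.

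Epithelial cells of the upper lobe had higher values of keratins of basal cells, the progenitors of airway lining, and lower values of genes of the air sac. KRT17 (log2 5.21 ± 1.64, 446 ± 265 v 11.97 CPM from 2 UMIs, same run 4.95), KRT5 (5.31 ± 1.84, 6.44), KRT15 (4.37, 4.99) and S100A2 (4.32, 5.43) were higher in IPF, as were the mucin gene MUC5B (3.87, 2.04), whose promoter carries a known IPF risk variant, and the protease gene MMP7 (3.28, 4.60). AGER, a marker of flat alveolar type 1 cells, was lower (−3.01 ± 0.87, 522 ± 358 v 4194 CPM, same run −3.15), and so was SFTPC of surfactant-making type 2 cells (−1.35 ± 2.06, 29733 v 75648 CPM, same run −3.04). HHIP (−3.41, −6.03), HSD17B6 (−3.51, −3.03), SBSPON (−3.78, −4.48), S100A8 (−3.39, −5.06), CDKN2B (−2.75, −3.30), BAMBI (−3.20, −4.01) and BANK1 (−2.45, −3.20) were also lower. AREG, MYO15B, DNAH1, CXCL14 and PER3 had no UMI in healthy epithelium and were at least 8.34, 6.56, 5.28, 5.13 and 3.68-fold higher against a floor of 17.9 CPM (library 5 at 34.0, 47.0, 40.7, 40.7 and 19.8 CPM). None of 11080 genes passed edgeR's quasi-likelihood test (0 passed, 564 at unadjusted p under 0.05, DESeq2 0, smallest adjusted p 0.943). Airway basal genes (4 of 6 higher, 3 over the list alone), alveolar type 1 genes (2 of 10 higher), type 2 genes (1 of 11) and ciliated genes (9 of 10) passed camera with its preset, each with adjusted p = 0.446 with an estimated correlation. In the healthy library 65.7% and 27.6% of epithelial cells lay in 2 clusters, and upper-lobe libraries 6 and 7 had 32.4% and 45.1% in another. The mix of epithelial cell types was not separated from these values, and 34.8% of tested genes had all 7 libraries on one side.

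Endothelial cells of the healthy library had higher values of 4 heat-shock genes, and ACKR1 and PLVAP were higher in the upper lobe. HSPA1A (log2 −3.60 ± 0.56, 62.1 ± 27.5 v 755 CPM, same run −3.98), HSPA1B (−4.83 ± 0.97, 153 ± 163 v 4241 CPM, same run −5.64), DNAJB1 (−3.25, −3.30) and HSP90AA1 (−2.38, −2.21), all chaperone genes, were lower in IPF. Heat-shock genes were higher in healthy mesenchymal cells too, and HSPH1 in healthy myeloid cells, and that library had the highest median mitochondrial share of all 9 (5.19%), so handling or quality of the tissue was not separated from these values. S100A9 (−4.39, −6.29), LYZ (−4.11, −4.26), PPBP (−4.14, −4.33) and CD14 (−2.34, −3.52), genes of myeloid cells or platelets, and MME (−3.99, −3.21) and IFIT2 (−2.96, −2.47) were lower too. ACKR1 (1.59 ± 0.92, 485 ± 216 v 159 CPM, same run 1.36) and PLVAP (1.88, 1.65) mark venules and were higher, and COL15A1 (1.86) was not higher in the same run (−0.08). TTLL3, SH3TC1, LRRC1, RHOT2 and LY6G5B had no UMI in the healthy sum and were at least 5.80, 4.65, 4.27, 4.38 and 4.19-fold higher against a floor of 31.9 CPM (library 5 at 132, 45.1, 177, 80.6 and 108 CPM). By edgeR 0 of 10459 genes passed (617 at unadjusted p under 0.05), with the smallest adjusted p for HSPA1A at 0.197 (7 of 7 libraries lower), and DESeq2 passed 1, HSPA1A (log2 −3.59, 7 of 7 lower, adjusted p = 0.0416). Without upper-lobe libraries 6 and 7 edgeR passed 4: HSPA1A (−3.40), HSPA1B (−4.38), DNAJB1 (−2.87) and LYZ (−3.68), and without library 2 it passed 1, S100A9 (−5.61). Stress (5 of 18 higher, 4 lower over the list alone) and interferon genes (2 of 19 higher, 1 lower over the list alone) had adjusted p = 0.153 with an estimated correlation, venous genes (7 of 8 higher) 0.332 and myeloid markers (2 of 11 higher, 2 lower over the list alone) 0.244. By fry, cell-cycle genes (0 of 5 higher) and T and NK markers (0 of 4 higher) had an adjusted p of 0.0433, and stress genes changed in mixed directions (adjusted p = 0.00641). The healthy sum held 102 cells and 95088 UMIs, with 90.2% of the cells in the cluster that also led in upper-lobe libraries 1 to 4, while libraries 6 and 7 had 82.0% and 84.3% in clusters of their own and library 5 had 45.2% in one led by vein genes such as ACKR1 and PLVAP. All 7 libraries lay on one side for 30.7% of tested genes.

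Myeloid cells of the healthy library had higher values of some interferon-response genes and of CES1, a gene of resident alveolar macrophages. IFIT1 (log2 −2.77, same run −2.30), IFIT2 (−2.26, −1.72), IFIT3 (−2.44, −1.54), OAS1 (−1.71, −1.24) and OAS3 (−1.91, −2.19), which act against viruses, were lower in the upper lobe, beside TNFSF10 (−2.54, −1.93). CES1, which encodes an esterase, was lower in the upper lobe (−2.87 ± 0.68, 242 ± 135 v 1756 CPM, same run −2.30), as were FABP4 (−1.39, −0.86), MARCO (−0.99, −0.27), FCN3 (−3.20, −3.48), HSPH1 (−1.92, −2.43) and IGFBP3 (−2.46, −0.55). SPP1, which marks macrophages of scarred lung, was close to equal (−0.20, −0.47). BPIFB1, DUSP4, CD109 and MAP3K14 had no UMI in healthy myeloid cells and were at least 6.48, 5.77, 5.76 and 3.95-fold higher against a floor of 10.6 CPM (library 5 at 85.3, 87.0, 58.2 and 16.7 CPM). By edgeR's quasi-likelihood test 0 of 10287 genes passed (339 at unadjusted p under 0.05, DESeq2 0, smallest adjusted p 0.756 for CD109). Interferon genes (1 of 19 higher, 5 lower over the list alone) and alveolar macrophage genes (0 of 10 higher, 1 lower over the list alone) passed camera with its preset, with adjusted p = 0.245 with an estimated correlation for each. Mesenchymal markers were higher for 10 of 12 (adjusted p = 0.536 with an estimated correlation), and free RNA or doublets were not separated from these values. In the healthy library 57.1% and 30.7% of myeloid cells lay in 2 clusters that led in upper-lobe libraries 1, 2 and 5, and upper-lobe libraries 6 and 7 had 81.9% and 75.0% in another; 22.4% of tested genes had all 7 on one side.

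Mesenchymal cells of the lower lobe had higher values of several matrix genes than those of the upper lobe. MMP11 (log2 4.96 ± 0.91, 927 v 38.1 ± 41.9 CPM, same run 7.32), STC2 (3.92, 2.43), CEMIP (3.13, 2.70), which breaks down hyaluronan, the stress hormone gene GDF15 (2.98, 2.94) and ITGA11 (2.22, 3.23) were highest. CTHRC1 (1.94 ± 0.95, 1349 v 352 ± 255 CPM, same run 3.04) was above all 7 upper-lobe libraries, beside COL1A1 (1.42, 2.45), COL3A1 (0.96, 2.06), POSTN (0.53, 1.70) and ACTA2 (0.51, 0.21). The airway genes KRT19 (−4.32, −2.58), MUC5B (−5.46, −0.52), MAPK15 (−4.85, −1.01) and BPIFB1 (−4.46, −2.78) and the clock gene PER3 (−4.60, −0.79) were lower, and MUC5B, MAPK15 and PER3 were nearer to the library of the same run. By edgeR's quasi-likelihood test 0 of 11292 genes passed (98 at unadjusted p under 0.05, DESeq2 0, smallest adjusted p 0.847), and 1 passed without upper-lobe libraries 6 and 7, GDF15 (2.69). Camera with an estimated correlation passed 2 lists, senescence and p53 genes (12 of 13 higher, adjusted p = 0.0438) and epithelial markers (0 of 16 higher, adjusted p = 0.0476). Epithelial cells were also a smaller share of the lower-lobe library, and free RNA or doublets were not separated from these marker values. Fibril collagens (14 of 16 higher, adjusted p = 0.296 with an estimated correlation) and fibrosis-fibroblast genes (6 of 6 higher, 0.256) passed with the preset alone. Upper-lobe libraries 3 and 4 shared their main mesenchymal cluster with the lower lobe (40.9%, 46.0% and 34.5% of cells), and another 20.2% of lower-lobe mesenchymal cells lay in a cluster led by MMP11, CTHRC1, ASPN and COL1A1, which drew 58.1% of its cells from the lower lobe. No paired analysis was possible with 1 lower-lobe library. Upper-lobe library 5, whose title shares a code with it, was counted among the 7 upper-lobe libraries, and 10.1% of tested genes had all 7 on one side.

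Epithelial cells of the lower lobe had higher values of some secreted and early-response genes. Among genes with a mean of at least 20 CPM, MSMB (log2 4.01, 1777 v 116 CPM, same run 5.69) and FCGBP (3.19, 2.17), both secreted in airways, were highest, with SLC16A12 (2.27, 0.74), NR4A2 (2.19 ± 0.35, 160 v 34.0 ± 6.27 CPM, same run 2.16) and ATF3 (2.07, 3.33). CDH2, a cadherin of basaloid cells in fibrosis, was higher too (4.34 ± 0.77, 68.7 v 4.97 ± 4.47 CPM, same run 4.62). HBA2 (−4.76, −1.83) and HBB (−4.02, −2.83), haemoglobin genes, MMP1 (−4.07, −4.80), S100B (−3.41, −1.15) and S100A2 (−3.34, −4.48) were lower. KRT17 (0.01, 0.15), MUC5B (−0.09, 1.71), MMP7 (−0.56, −1.90), SFTPC (0.40, 2.10) and AGER (0.94, 1.08) were nearer to the upper-lobe mean. By edgeR's quasi-likelihood test 0 of 11442 genes passed (85 at unadjusted p under 0.05, smallest adjusted p 0.942), and DESeq2 passed 2, among them NR4A2 (2.15, above 7 of 7 libraries, adjusted p = 0.0311). Aberrant basaloid genes (10 of 12 higher, 1 over the list alone, adjusted p = 0.118 with an estimated correlation), airway basal genes (0 of 6 higher, 0.269), type 2 genes (11 of 11 higher, 0.430) and stress genes (15 of 18 higher, 0.269) passed camera with its preset alone. The lower lobe had 41.1% of its epithelial cells in the cluster that also led in upper-lobe libraries 2, 3 and 4, and 11.8% of tested genes had all 7 on one side.

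On GRCh38 (GENCODE 44) the protein-coding genes named first lie as follows. CTHRC1 is on chromosome 8 at 103371538 to 103382989 (plus strand), COL1A1 on 17 at 50184101 to 50201632 (minus), POSTN on 13 at 37562583 to 37598844 (minus), MMP11 on 22 at 23768226 to 23784316 (plus) and LDB3 on 10 at 86666785 to 86736072 (plus). FGF7 is on 15 at 49423237 to 49488775 (plus), SFRP2 on 4 at 153780591 to 153789083 (minus), BMP5 on 6 at 55753653 to 55875590 (minus) and WNT2 on 7 at 117275451 to 117323152 (minus). KRT17 is on 17 at 41619442 to 41624842 (minus), AGER on 6 at 32180968 to 32184322 (minus) and SFTPC on 8 at 22156913 to 22164479 (plus).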

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

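No test in this part was chosen after its result was seen. Each value below is the gap between the outermost upper-lobe library and its nearest neighbour, divided by the range of all 7, and it is listed where it exceeded Dixon's 95% critical value. Chance alone lists about 1 in 20 groups of libraries. Of 20 library measures 5 stood out, and of 191 gene values 30.

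Library 3 was the deepest, with gaps of 0.642 for total UMIs, 0.682 for median UMIs and 0.601 for median genes. Library 4 had the most lymphoid cells, 40.4% against 20.03% in the next library (0.602). Library 6 had the most unnamed cells, 11.9% against 3.85% (0.686), and 96.0% of 453 cells in an unnamed cluster led by mitochondrial genes came from it.

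Within cell classes, PCOLCE2 (0.709) had no UMI in mesenchymal cells of library 1, which at that depth does not rank it below the others, and HSPH1 (0.626) was lowest in those of library 5. In epithelial cells KRT17 was lowest in library 7, 72.4 against 243 CPM (0.575), and so was MMP1 (0.580), while S100B was highest in library 1, 140.0 against 5.31 CPM (0.748). In endothelial cells S100A9 was highest in library 2, 527 against 79.2 CPM (0.582), and ACKR1 lowest in library 7 (0.577). In myeloid cells CD109 was lowest in library 1 (0.590) and FABP4, a gene of alveolar macrophages, in library 6, 7.55 against 204 CPM (0.620).

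Between cells with and without a CTHRC1 UMI, libraries 1 and 7, with 25 and 22 such cells, held most of the outermost values. All values named here for libraries 1 and 7, and FGFR4 in library 2, come from sums with no UMI of the gene in cells with a CTHRC1 UMI, so the gaps are set by the pseudocount of 1 CPM and the values are bounds. In library 1 these were MCAM (0.587), LAMA5 (0.632), MYH11 (0.875), DES (0.720), CNN1 (0.828), PDGFA (0.774) and SDC1 (0.757). In library 7 they were P4HA3 (0.664), NID2 (0.634), COL15A1 (0.741), DPT (0.712), SOD2 (0.860), INHBA (0.708), EFNA5 (0.741), ITGA11 (0.645), PDIA6 (0.867) and MANF (0.853). In library 2, with 50 such cells, FGFR4 (0.814) and PHLDA3 (0.695) stood apart, and in library 6, with 66, C7 (0.707).

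For CCR2 the difference between mesenchymal cells and the mean of the 4 other classes was largest in library 1 (log2 −4.52 against −2.16 in the next, 0.638), where mesenchymal cells held no CCR2 UMI, so it is also set by the pseudocount.

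VEGFA, an angiogenic growth factor gene, was lower in cells with a CTHRC1 UMI in all 7 upper-lobe libraries (log2 −0.60) and higher in the lower-lobe library (0.14). This difference between lobes was not tested.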

How the results depend on the processing

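The alternatives named in processing as chosen after the data were seen are the top doublet scores, libraries 6 and 7 left out, unlisted genes as 0, depth matching, the mixed sub-cluster left out, lymphoid kinds apart and run as a block. No paired analysis was possible between tissue groups because the healthy and lower-lobe groups hold 1 library each. Of the 72 named genes of cells with a CTHRC1 UMI, ASPN, COL12A1, LRRC17, MMP11 and P4HA3 passed under every alternative in which they were tested, 63 kept their direction and 9 reversed. The 25 named signalling genes passed wherever tested, with 96 signalling genes past the threshold without the library block and 117 without library 1. Named values of the epithelial comparison with the healthy library kept their direction in all 400 alternative values. Depth was low in the healthy library, where 61 mesenchymal cells held 61045 UMIs, against 1480 cells and 2681440 UMIs in the lower-lobe library. On simulated data the mesenchymal comparison recovered 0% of 8-fold changes for the healthy library and 30.9% for the lower-lobe library. Depth and the lack of replicates were not separated. Of all cells, 14.04% had under 500 genes.

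For cells with a CTHRC1 UMI, 732 genes became 397 by DESeq2, 72 with cells thinned to one depth, 195 with cells matched on depth (1770 genes tested), 113 matched without library 3, and 308 to 755 on leaving out 1 upper-lobe library (456 without library 3). It became 7 with no replicate block. Other settings gave 624 (without libraries 6 and 7) to 839 (no filter). In endothelial cells 0 genes by edgeR became 1 by DESeq2, 4 without libraries 6 and 7, and 0 to 1 on leaving out 1 upper-lobe library. Without libraries 6 and 7 the lower-lobe mesenchymal count became 1, and by DESeq2 the lower-lobe epithelial count became 2. Fewer genes were tested after thinning and matching; otherwise the cause was not tested.

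Against the healthy library, mesenchymal CTHRC1 reversed to 0.0383 by marker score, 0.23 without libraries 6 and 7 and 0.31 with the lower-lobe library among the IPF libraries (−0.42 to 0.0771 on leaving out 1 library). Mesenchymal ACTA2 reversed to −0.20 without libraries 1 and 2 (−0.24 to 0.21 on leaving out 1). Myeloid SPP1 reversed to 0.0535 with the top 6% of doublet scores removed. In lower-lobe epithelium KRT17 reversed to −0.0309 with RLE, −0.0137 by DESeq2, −0.0146 with at least 500 genes, −0.0171 without libraries 6 and 7 and −0.0475 with unlisted genes as 0 (−0.24 to 0.20 on leaving out 1). There, without libraries 6 and 7, MUC5B reversed to 0.18 (−0.32 to 0.22 on leaving out 1) and SFTPC to −0.0175. With run as a block, which rests each comparison on library 5, 0 genes passed in all 6 comparisons with the healthy or lower-lobe library (111 to 448 at unadjusted p under 0.05 by edgeR), endothelial COL15A1 reversed to −0.0769 and lower-lobe epithelial MUC5B to 1.72. None of these values passed a threshold, and the cause was not tested.

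Among fibroblasts only, with 719 genes past the threshold, ACTA2 reversed to 1.08, NOTCH3 to 0.79, CNN1 to 0.69, DES to 0.54, MYH11 to 0.37, PDGFA to 0.17, RGS5 to 0.14, CSPG4 to 0.11 and LAMA5 to 0.0721. Cells named smooth muscle or pericytes are left out there by construction, and unnamed cells are kept. All of these genes but PDGFA and LAMA5 are among the markers that named the cells left out.

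With at least 500 genes per cell, shares became 31.8% mesenchymal, 11.8% epithelial, 15.98% endothelial, 14.3% myeloid, 23.5% lymphoid and 0.672% unnamed in the lower lobe, and 43.99% myeloid and 3.07% lymphoid in the healthy library. By marker score they became 26.8% mesenchymal, 8.42% epithelial, 29.9% lymphoid, 2.34% mast, 4.61% mesothelial and 0% unnamed in the lower lobe. By marker score the healthy library had 20.8% epithelial, 13.4% endothelial, 1.80% mast and 7.86% mesothelial cells, and the upper lobe 3.04% mast and 4.90% mesothelial. At higher resolution adventitial fibroblasts became 11.1% in the upper and 8.92% in the lower lobe, where alveolar became 22.4% and fibrosis-type 22.6%. Unthinned CTHRC1 shares became 18.5% in the upper and 35.3% in the lower lobe, and taken by kind the lymphoid share was 5.98% in plasma, 1.12% in T and NK and 1.10% in B cells. The cause was not tested.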

Other observations

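The tests below on genes testable at matched depth and on plasma cells were chosen after the results were seen, as was the bound used to read the swaps. The swaps and the match on depth were chosen before their own results. Lymphoid cells of the libraries differed in kind. Plasma cells, which secrete antibodies, held 15.3%, 11.0%, 3.22%, 11.6%, 5.15%, 1.28% and 6.20% of cells in upper-lobe libraries 1 to 7, 3.27% (2.01 to 5.01%) in the healthy and 6.92% in the lower-lobe library. T and NK cells ranged from 0.601% to 20.9% in the upper lobe, with 1.96% in the healthy and 14.5% in the lower-lobe library. B cells held 0 of 611 healthy cells (which allows up to 0.491%), at most 7.85% of upper-lobe cells and 6.60% of lower-lobe cells. Plasma markers were higher for 5 of 5 genes in upper-lobe mesenchymal (adjusted p = 0.674 with an estimated correlation), epithelial (0.446) and myeloid cells (0.536). None of these shares was tested.

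Among upper-lobe mesenchymal cells with a CTHRC1 UMI, epithelial and myeloid markers fell for 1 of 11 each (myeloid 2 over the list alone), with 0 of 5 endothelial markers changed.

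The gene differences of cells with a CTHRC1 UMI could come from chance or from depth, since cells with more UMIs more often show a given gene. Swapping the 2 sums within libraries gave as many genes in 1 of 64 splits, the real one, and at most 519 genes in another, so chance does not account for the count. Against cells of similar depth 24.04% of the genes stayed past the threshold, or 62.6% (176 of 281) of those that could be tested, with the same sign in all 281. Cells picked only for their depth differed from the rest in 2 of 5997 genes, and in 5 of 6138 without library 3, where the match was poor (medians of 8862 and 2447.5 UMIs) and without which all 207 kept their sign. Depth alone gave few genes, but how much it adds stayed open, since only 49.8% of the testable genes (103 of 207) passed without library 3, and no biological explanation was tested.

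CTHRC1 UMIs in plasma cells could be RNA of mesenchymal cells free in the droplets. In the 8 libraries with such UMIs, plasma cells held 6.82% to 935% of the mesenchymal CTHRC1 level, against 0.242% to 11.2% for COL1A1, COL3A1 and COL1A2. The share was over 3 times that of each collagen gene in these 8 libraries, of which the healthy library and upper-lobe library 2 held 3 and 6 such UMIs. Upper-lobe library 1 was left out by this choice. Its 51 plasma cells held 0 CTHRC1 UMIs, with the collagen genes at 1.92% to 5.55% of the mesenchymal level. In the 8 libraries, free RNA with the collagen content of mesenchymal cells does not account for the CTHRC1 UMIs. In 3 libraries plasma cells were at or above the mesenchymal level. The excess was not limited to plasma cells. In endothelial cells the CTHRC1 share was above each collagen gene in upper-lobe library 7 (97.6% against 5.56% to 8.86%) and library 6 (40.4% against 5.81% to 7.75%). The same held in library 5 (18.5% against 2.05% to 3.88%), library 3 (4.21% against 1.42% to 2.80%) and the lower-lobe library (10.04% against 5.29% to 7.30%). The share was also above each in library 2 (11.4% against 5.28% to 10.6%) and the healthy library (8.02% against 2.43% to 5.79%), from 4 and 3 UMIs. It was not above each of them in library 1 (5.86% against 6.83% to 16.2%) and library 4 (6.00% against 3.66% to 7.17%). Expression in plasma cells and off-target binding of a probe to abundant plasma-cell RNA are candidate explanations for the plasma cells alone, and were not tested.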
